A study of Mus musculus with 8 samples.

How the data were processed

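Expression was profiled on 1-colour oligonucleotide arrays in 8 samples of mouse interfollicular epidermis, 4 from G9a cKO and 4 from WT animals. Per the labels' protocols, DMBA (0.25 mg/ml) and TPA (0.02 mg/ml) were applied to shaved back skin, 200 µl of each, weekly for 6 weeks from an age of 8 weeks. The animals are labelled as 15 weeks old. RNA was extracted with TRIzol, 25 ng were amplified with WTA2 in 17 cycles, and 8 µg of cDNA were fragmented and biotinylated, per the labels' protocols. The values were made by the authors with RMA, per the submitters' processing notes; its version and settings are not given in the sources used here. RMA corrects background, normalises between arrays by quantiles and summarises perfect-match probes. The deposited values were taken as log2 expression per probe set: they run from about 3.06 to 13.2, with array medians of 5.72 to 5.80, and the base of the logarithm is inferred from this range. Scanner files were not used here, so the scale and centring could not be set against them. Quantile normalisation makes the overall distributions of the arrays alike, so a shift of all genes together could not be seen in these values.

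The table holds 45141 rows, of which 104 control probe sets were left out and 45037 tested. The platform annotation pairs 28898 of the tested probe sets with 1 gene and 551 with several, and 15588 are unnamed here. Entrez numbers of 28689 of the 1-gene probe sets were found in a reference table of mouse genes (assembly GRCm38.p6), which supplied current symbols; the others kept the symbol of the annotation. This table was otherwise used for older symbols of listed genes, for the chromosome of genes and for their order, and no coordinate from it is reported. For the gene table, each of 17097 genes was represented by the probe set with the highest mean over the 8 arrays. Of these genes, 7180 had more than 1 probe set to choose from. The mean includes the cKO arrays, so among probe sets of similar level the rule favours one that rises in cKO. No filter on dim probe sets was applied. The arrays give no read depth, so that their number, 4 per group, limits the precision.

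Groups were taken from the labels. cKO was compared with WT with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, on the gene table and separately on all probe sets. Errors of fold changes are standard errors from this fit, and levels are means ± SD over 4 arrays. The titles name the genotype of the animal and a replicate number, with no word on litters or days. They do not say whether each replicate is a separate animal, so that p-values measure the spread between these samples. Exact permutation tests were two-sided over the 70 arrangements of 4 against 4. The tests, the gene lists and the alternatives were fixed before the data were examined, except where said otherwise. Of 48 lists with 1491 entries, 1288 measured, 46 name pathways or cell types and 2 are technical checks. Lists were tested with limma's camera with a preset correlation between genes of 0.01, and for each list the members past the threshold over all genes and adjusted over the list alone were counted.

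Of the genes that the rule below selects, 1 of the 12 largest rises is not reported here. The genes named in the text are Ehmt2 and the genes of its partner proteins Ehmt1, Wiz and Zfp644; the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap; and, for each list described, up to 4 members, those past the threshold over all genes first and then by size of change. Genes outside this rule, which were chosen after their values were seen, are Pole2, Prim1, Afp, Snurf, the other pairs of neighbouring genes and the X-linked genes Bex1 and Maob.

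The procedure was tested on simulated data for cKO against WT: 20 runs over 17097 genes, each with 200 changed genes. Of genes changed by 0.5 on the log2 scale 84.7% were recovered, of those changed by 1.00 98.0% and of those changed by 2.00 100%, and 4.91% of the calls were false. The simulated noise was independent for each gene and had no structure between arrays, so these rates need not hold for the real arrays. Camera called 0 of 920 unchanged lists and 20 of 20 lists lowered by 0.1, in simulated values without correlation between genes. Alternatives were the replicate number as a block, filters on dim genes, another normalisation, median centring, a prior with trend, array weights, other rules for the probe set of a gene, other thresholds, other list tests and leaving out each array. Plots were drawn with matplotlib 3.10.9.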

Results

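Gene expression was measured in interfollicular epidermis, the skin epithelium between hair follicles, of mice whose back skin had received the carcinogen DMBA and the tumour promoter TPA but had not yet formed tumours. In 4 arrays the RNA came from animals with a conditional knockout (cKO) of G9a, the histone H3 lysine 9 methyltransferase encoded by Ehmt2, and in 4 arrays from wild-type (WT) animals. The design asks which genes differ in expression when G9a is lost at this stage. Each sample was hybridised to its own 1-colour array, and the array medians lay between 5.72 and 5.80 on the log2 scale. Arrays of the same group correlated with r between 0.996 and 0.998 across genes in cKO and between 0.995 and 0.998 in WT, against 0.993 to 0.997 between the groups. No pair of arrays was a duplicate, since the smallest SD of the difference between 2 arrays was 0.124 over 17097 genes. The first principal component held 36.5% of the variance and the second 25.0%. WT 4 stood at 7.37 on the first, within the range of the cKO arrays (-0.893 to 12.7) and apart from the other WT arrays (-14.7 to -10.0), and at the far end of the second (-16.3). cKO 2 stood at -0.893 on the first, below the other cKO arrays (3.40 to 12.7), and at the opposite end of the second (14.2).

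Ehmt2 itself was much lower in the knockout at 1 of its 2 probe sets. Probe set 1460692_PM_at read 6.61 ± 0.36 in cKO and 9.49 ± 0.28 in WT (log2, mean ± SD, n = 4 each), so that it fell by 2.88 (SE 0.19), which is 7.37-fold, with a limma adjusted p of 0.000244. All 4 cKO arrays, at 6.30 to 7.07, lay below all 4 WT arrays, at 9.25 to 9.77, and the exact permutation test gave p = 0.0286, the smallest that 4 against 4 allows. The other probe set, 1426888_PM_at, read 8.36 ± 0.06 in cKO and 8.35 ± 0.12 in WT (log2 fold change 0.01, limma adjusted p = 0.996, exact p = 0.886). The labels do not say which part of Ehmt2 was deleted, and a probe set outside that part checks nothing. The genes of its partner proteins did not pass the test: the log2 fold change was 0.03 for Ehmt1, the related methyltransferase GLP, 0.03 for Wiz and 0.04 for Zfp644, with limma adjusted p of 0.972, 0.982 and 0.956. The signs of Ehmt1 and Wiz turned when single arrays were left out, and that of Zfp644 when all its probe sets were averaged.

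**Figure D1:**
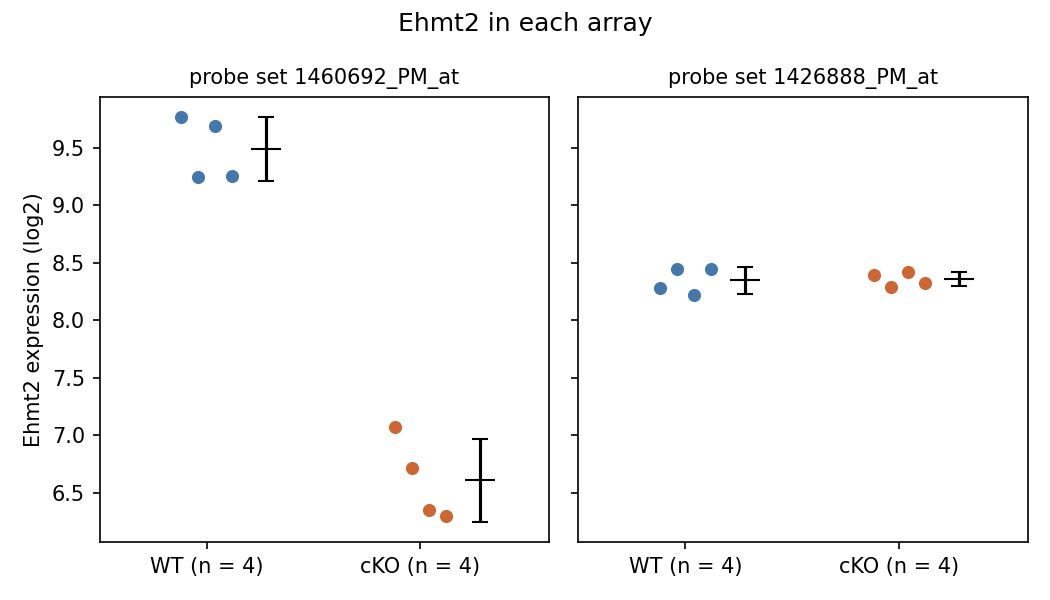
Expression of Ehmt2 (log2) in each array at its 2 probe sets, with 4 WT and 4 cKO arrays per panel; points are arrays and the black marks are the group mean ± SD. At 1460692_PM_at the cKO arrays lie between 6.30 and 7.07 and the WT arrays between 9.25 and 9.77, while at 1426888_PM_at the groups overlap.

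Loss of G9a was accompanied mainly by higher expression: of 17097 genes tested, 135 rose and 32 fell in cKO (limma, Benjamini-Hochberg adjusted p under 0.05), so that 80.8% of the 167 changed genes were higher. The rises also reached further, with 33 genes at least 2-fold higher and 4 at least 2-fold lower. The median change was 0.52 among genes that rose and -0.51 among genes that fell (log2). Minar2, whose product is a membrane protein that binds NOTCH2, had the largest rise in the gene table, 17.1-fold at the probe set standing for it. Its other probe set changed by 0.89 (log2). Akr1c13, an aldo-keto reductase, rose 13.5-fold, while Skint10, of the Skint family of epidermal membrane proteins, had the largest fall in the gene table, 2.50-fold. In each of the 167 genes all 4 cKO arrays lay on one side of all 4 WT arrays. Selection by p-value favours such separation, so it is no separate support. Over all genes it held for 978, or 5.72%, where chance gives 2.86%. Ehmt2 is not among the 167, because the probe set that stands for it in the gene table is the one that did not differ. Without reduction to genes, 210 of 45037 probe sets changed, 177 higher and 33 lower. The number of changed genes was 89 without WT 1, 84 without WT 3, 98 without cKO 2 and 81 without cKO 3, was 69 in the upper 50% of genes by mean, and was 604 with array weights. It was 430 without both cKO 2 and WT 4, a setting chosen after seeing that a regrouping in which these arrays change places gives 478 genes; the 6 arrays left are parted alike by both groupings.

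The 12 largest rises began at WT levels between 3.86 and 6.76 (log2), which were not shown to lie above background, so that their sizes and order are uncertain and depend on the probe set. Minar2 went from 3.86 ± 0.51 in WT to 7.96 ± 0.34 in cKO, a log2 fold change of 4.10 (SE 0.25, limma adjusted p = 0.000133, n = 4 each). Its second probe set changed by 0.89 and read higher in WT, at 4.32 ± 0.16. The first set thus stands for Minar2 only through its cKO values. Akr1c13 went from 5.20 ± 0.36 to 8.95 ± 0.38 (3.75, SE 0.21) and its neighbour and close relative Akr1c12 from 6.01 ± 0.38 to 8.30 ± 0.22 (2.28, SE 0.18). The other probe set of Akr1c12 changed by 3.38, and this set stood for the gene without any 1 of the WT arrays, when its change was up to 3.47. Gpa33, a surface antigen known from intestinal epithelium, rose by 2.91 (SE 0.18) at 1 probe set and by 1.68 at its other, and Gkn1, a secreted protein of the stomach lining, rose by 2.17 (SE 0.19). The amino acid transporter gene Slc38a4 rose by 2.65 (SE 0.19), from 6.76 ± 0.37 to 9.41 ± 0.27, and the gasdermin family member Gsdmc2 by 2.64 (SE 0.18). The TRIM family genes Trim30d and Trim30a rose by 2.16 (SE 0.24) and 2.13 (SE 0.22), Gm8126 by 2.42 (SE 0.16) and Efcab1 by 2.05 (SE 0.17). The other probe set of Trim30a changed by 1.33, other probe sets of Trim30d changed by 0.90 and stood at 0.42, which did not pass (limma adjusted p = 0.0953), and those of Efcab1 changed by 2.05 and 0.25. Limma adjusted p for the 12 largest rises, 11 of which are named here, ran from 0.000133 to 0.00281, and all 12 stayed past the threshold whichever array was left out. Akr1c12 with Akr1c13, Trim30a with Trim30d, and Gsdmc2 have near relatives whose transcripts their probes could also bind, so the share of each gene is uncertain. The probe sets standing for Minar2, Gkn1 and Gm8126 carry the suffix _x_at, which marks probes that other transcripts may share. What these rises owe to the named genes is likewise uncertain.

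The 12 largest falls were smaller and began at WT levels between 5.20 and 11.3 (log2). Skint10 fell by 1.32 (SE 0.23) and Tesc, the gene of the calcium-binding protein tescalcin, by 1.30 (SE 0.24). Igfbp3, a binding protein for insulin-like growth factors, fell by 1.01 (SE 0.10), from 10.9 ± 0.08 to 9.94 ± 0.22, with a limma adjusted p of 0.00133. The clustered protocadherin gene Pcdhb19 fell by 1.02 (SE 0.11). The homeobox genes Hoxb8 and Hoxb6 fell by 0.93 (SE 0.13) and 0.65 (SE 0.08). Dio2, the deiodinase that activates thyroid hormone, fell by 0.87 (SE 0.12), and Crlf2, which encodes a subunit of the receptor for the cytokine TSLP, fell by 0.75 (SE 0.06). Nop53, a ribosome biogenesis factor, fell by 0.73 (SE 0.06) and was lower at all 3 of its probe sets, while a further probe set of Tesc at -0.33 (limma adjusted p = 0.331) and 1 of the 3 of Dio2 at -0.27 (adjusted p = 0.0801) did not pass. Ptprz1, a receptor tyrosine phosphatase, fell by 0.66 (SE 0.07), Nccrp1 by 0.69 (SE 0.13) and Thbd, thrombomodulin, by 0.61 (SE 0.11). Limma adjusted p ran from 0.000569 for Crlf2 to 0.0452 for Tesc. Of these 12 genes 7 stayed past the threshold whichever array was left out; Dio2 lost it without WT 1 (adjusted p = 0.0511), and Skint10, Tesc, Nccrp1 and Thbd lost it without any of several arrays (highest adjusted p = 0.131, 0.156, 0.122 and 0.143) and did not pass in the fit over all probe sets.

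**Figure D2:**
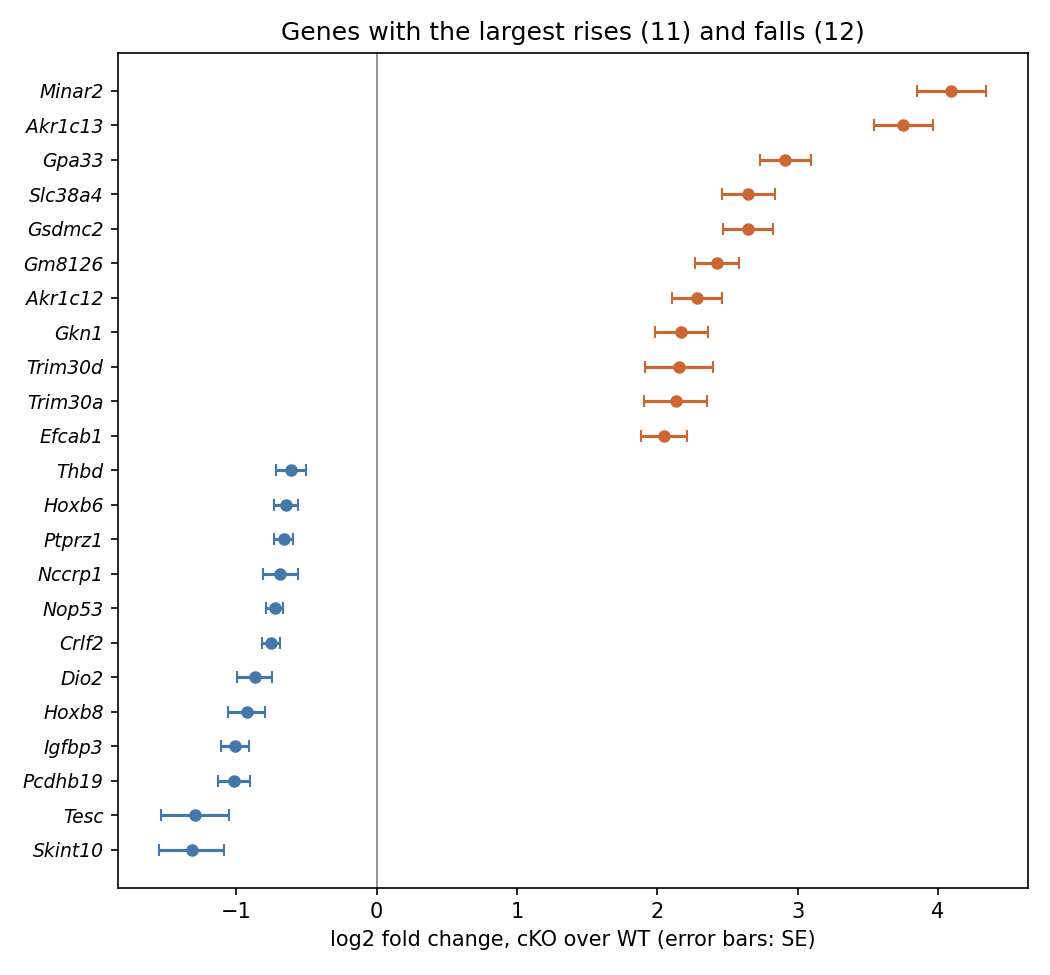
Log2 fold change, cKO over WT, of 11 of the 12 genes with the largest rise and the 12 with the largest fall among changed genes whose groups do not overlap; points are estimates from 4 arrays per group and bars are standard errors. Rises extend to 4.10 for Minar2 and falls to -1.32 for Skint10.

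In the list of imprinted genes, which are expressed from 1 parental copy, 2 of 25 measured members rose, none fell and 23 did not pass. The list does not hold all imprinted genes, and Slc38a4 and Snurf, which rose, are not in it. Snrpn rose by 1.14 (SE 0.09, limma adjusted p = 0.000520) and Peg3, a zinc finger gene expressed from the paternal copy, rose by 0.60 (SE 0.08, adjusted p = 0.00658). Peg3 read 3.96 ± 0.11 in WT and 4.56 ± 0.14 in cKO, low levels that were not shown to lie above background. Of the further probe sets of these genes, 1 of Snrpn at 0.31 and that of Peg3 at 0.27 did not pass in the fit over all probe sets (adjusted p = 0.154 and 0.201). Adjusted over the list alone 3 members were higher, the third being Impact at 0.29 (SE 0.07). Of 34 measured germline genes, 1 rose over all genes tested and 1 adjusted over the list alone: Rhox5, an X-linked homeobox gene of reproductive tissues, at 0.45 (SE 0.07, adjusted p = 0.0163). Rhox5 lost the threshold without WT 3, cKO 2 or cKO 3 (highest adjusted p = 0.0699). As lists, imprinted and germline genes did not shift against other genes (limma camera adjusted p = 0.167 and 0.902). Limma's fry for changes in either direction, a list test added after the data were seen, called the imprinted list (adjusted p = 0.000103). Here and below, this test asks whether members differ at all, not whether they differ more than other genes. Single members already called can therefore carry it. None of the 27 measured genes of the H3K9 methylation machinery passed, over all genes or adjusted over the list alone; the furthest was Zfp462 at 0.46 (SE 0.18, limma adjusted p = 0.424; other probe sets 0.11 and 0.12), which passed without WT 2 (adjusted p = 0.0268).

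Most epidermal markers did not pass the test. Of 35 granular and cornified layer genes 2 fell and 33 did not pass: Nccrp1, given above, and Cdsn, the corneodesmosome protein corneodesmosin, which fell by 0.38 (SE 0.07). Adjusted over the list alone 3 were lower, the third being the kallikrein protease gene Klk7 at -0.54 (SE 0.13). Of 37 genes of activated keratinocytes, 1 fell, over all genes and adjusted over the list alone: Il1f9, an interleukin 1 family cytokine, by 0.45 (SE 0.08). The stress keratin gene Krt6b, at -1.01 (SE 0.38, limma adjusted p = 0.408), did not pass, but did without WT 4 (-1.43, adjusted p = 0.00764). Of 24 basal keratinocyte genes, 1 rose, the chemokine gene Cxcl14, by 0.32 (SE 0.06; its other probe set stood at 0.21), and adjusted over the list alone 1 was higher and 1, Sox6 at -0.32 (SE 0.08), was lower. Of 27 genes of hair follicle stem cells and outer root sheath, 1 rose, the secreted Dickkopf family member Dkk3, by 0.47 (SE 0.06, adjusted p = 0.00933), and adjusted over the list alone 2 were higher. The other probe set of Dkk3, at 0.40, did not pass in the fit over all probe sets (limma adjusted p = 0.112). None of the 21 spinous, 26 hair shaft and inner root sheath or 23 sebaceous genes passed, over all genes or adjusted over the list alone. Camera called none of these lists, fry for either direction called those of hair follicle stem cells (adjusted p = 0.00186) and of the granular and cornified layers (0.0194), and the single calls of Cdsn, Il1f9 and Cxcl14 were lost without most of the arrays (highest adjusted p = 0.135, 0.154 and 0.164). Cdsn, Il1f9 and Cxcl14 also did not pass in the fit over all probe sets (limma adjusted p = 0.0740, 0.0702 and 0.0712).

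Cytokine genes went both ways. Of 40 measured cytokines and chemokines, 2 rose, 2 fell and 36 did not pass. The interleukin 1 family genes Il18 and Il33 rose by 0.58 (SE 0.11) and 0.38 (SE 0.06), while Tslp, the epithelial cytokine bound by the Crlf2 receptor, fell by 0.61 (SE 0.11) and Il1f9 by 0.45. Adjusted over the list alone 3 were higher and 2 lower. Each of these calls was lost without 5 or more of the 8 arrays, with a highest limma adjusted p of 0.160 for Il18, 0.113 for Il33 and 0.120 for Tslp. In the fit over all probe sets Il33 passed (limma adjusted p = 0.0465), while Il18, Tslp and Il1f9 did not (0.0755, 0.0545 and 0.0702). Of 40 interferon-stimulated genes, 1 rose, over all genes and adjusted over the list alone: Trim30a, given above; the next in size, Zbp1, stood at 0.25 (SE 0.19, adjusted p = 0.808; other probe set 0.05), and its sign turned without both cKO 2 and WT 4. Of 22 genes of the AhR and xenobiotic response, 1 rose, over all genes and adjusted over the list alone: the glutathione transferase gene Gsto1, by 0.23 (SE 0.04), a call lost without 7 of the 8 arrays (highest adjusted p = 0.152). Of 24 NRF2 targets none passed over all genes, and adjusted over the list alone 1 was higher, Gclm at 0.44 (SE 0.09), and 1 lower. Of 34 EMT and invasion genes, 1 rose, the collagen gene Col5a2, by 0.33 (SE 0.06; its other probe set stood at -0.01), a call lost without 6 of the 8 arrays (highest adjusted p = 0.159), and adjusted over the list alone 2 were higher and 1 lower. None of 32 immediate early and AP-1 genes, 27 Ras/MAPK feedback targets, 26 Wnt/beta-catenin targets, 19 Notch pathway genes or 58 ribosomal protein genes passed, over all genes or adjusted over the list alone. Gsto1 and Col5a2 did not pass in the fit over all probe sets (limma adjusted p = 0.0591 and 0.0659). Limma camera called none of the lists in this paragraph, and fry for either direction called those of cytokines and chemokines (adjusted p = 0.00116), of the AhR and xenobiotic response (0.0163) and of NRF2 targets (0.0344).

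The lists of cell cycle and DNA repair genes stood lower in cKO than other genes by limma camera with a preset correlation between genes, but with an estimated correlation no list was called (adjusted p = 0.994 for each). None of 37 genes of the G1/S phase, 45 of the G2/M phase, 51 of DNA repair or 25 of the unfolded protein response passed over all genes, and none of 35 p53 targets did. Adjusted over the list alone, 3 G1/S genes were lower, E2f2 at -0.29 (SE 0.07), Pole2 at -0.26 (SE 0.07) and Prim1 at -0.18 (SE 0.05), and 3 p53 targets were higher, Eda2r at 0.42 (SE 0.10), Dcxr at 0.33 (SE 0.07) and Psrc1 at 0.24 (SE 0.06); none in the other 3 lists passed. Other probe sets stood at -0.09 for Pole2, at -0.10 for Prim1 and at 0.20 and 0.07 for Psrc1. The list medians were -0.11 for G1/S, -0.06 for G2/M, -0.04 for DNA repair, -0.07 for the unfolded protein response and 0.07 for p53 targets (log2). Limma camera with a preset correlation called these 5 of 46 lists, with adjusted p of 1.1e-08, 0.000607, 0.000760, 0.000760 and 0.0375. The exact permutation test of the list mean per array, 4 against 4, gave p = 0.143, 0.314, 0.114, 0.371 and 0.0857 in the same order. The camera call of G2/M was lost without WT 2 (median -0.01, adjusted p = 0.0901), and that of p53 targets without WT 4 (median 0.01, adjusted p = 0.517) or cKO 2 (0.06, adjusted p = 0.227). Medians moved by over 1.5 times for G1/S to -0.07 without cKO 4, -0.18 without WT 4 and -0.18 without cKO 1, for G2/M to -0.03 without cKO 4 and -0.11 without WT 4, for DNA repair to -0.08 without WT 3 and -0.07 without cKO 1, and for the unfolded protein response to -0.04 without WT 3, -0.14 without WT 4 and -0.11 without cKO 2.

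**Figure D3:**
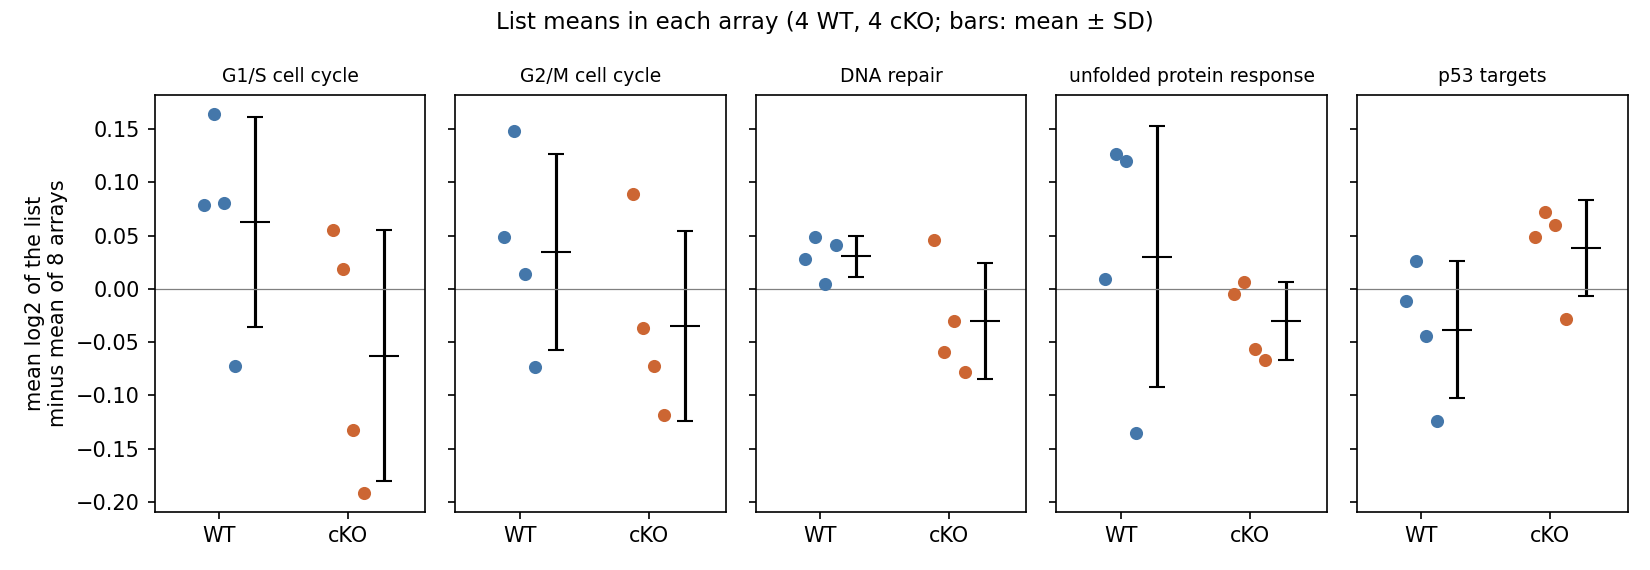
Mean log2 expression of the 5 gene lists called by camera with the preset correlation, in each array, minus the mean of all 8 arrays; points are 4 WT and 4 cKO arrays and black marks are the group mean ± SD. The groups overlap in each panel, with exact permutation p between 0.0857 and 0.371.

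Lists of markers of other cell types that the preparation could hold were not called by limma camera. Over 15 such lists with 280 measured members (a gene may be in several), the member that passed over all genes was Col5a2, which stood among the fibroblast genes. The list medians reached at most 0.04, for Langerhans and other dendritic cells, where Cd74 and H2-Aa, of the antigen presentation machinery, stood at 0.49 (SE 0.31) and 0.40 (SE 0.24; other probe sets 0.32 and 0.11), and Fscn1, the gene of the actin-bundling protein fascin, at -0.48 (SE 0.28; other probe sets -0.43 to -0.04), and did not pass. Adjusted over the list alone 1 gene was higher in each of the lists of B cells (Bank1, 0.25), skeletal muscle (Myh2, 0.22), smooth muscle (Acta2, 0.41, with 0.07 at its other probe set) and fibroblasts (Col5a2, 0.33). Fry for either direction called the lists of skeletal muscle and fibroblasts (adjusted p = 0.0141 and 0.0148). The skeletal muscle list averaged 5.28 ± 0.01 in cKO and 5.26 ± 0.02 in WT (log2, n = 4 each), with all cKO arrays above all WT arrays (exact permutation p = 0.0286, adjusted over the lists 0.910). None of the 45 measured genes that lie beside Ehmt2, and none of 8 measured Y-linked genes and Xist, passed over all genes. The furthest beside Ehmt2 were C2 at -0.49 (SE 0.12, limma adjusted p = 0.115) and Tnxb at 0.31 (SE 0.11, adjusted p = 0.353).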

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

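Values far from the other 3 arrays of their group were found in 5 of the 156 groups of 4 arrays that were tested, where chance gives about 7.8. Hoxb6 read 5.75 in cKO 1, with the other cKO arrays between 5.58 and 5.60. Snrpn read 8.83 in cKO 3, with the others between 8.59 and 8.62. Tslp read 6.05 in WT 1, against 6.45 to 6.49 in the other WT arrays. Gclm read 7.32 in cKO 4, against 7.61 to 7.66 in the other cKO arrays. Bex1 read 4.69 in WT 2, against 4.13 to 4.14 in the other WT arrays.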

How the results depend on the processing

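The setting that left out both cKO 2 and WT 4 and fry's p for either direction were added after the data were seen. Where a count changed, the cause was not tested unless fewer genes, fewer arrays or another threshold give it by construction. Numbers of changed genes, higher and lower, were 69 (57 and 12) in the upper 50% by mean, 604 (463 and 141) with array weights, 430 (316 and 114) without both cKO 2 and WT 4, 280 (224 and 56) at an adjusted p under 0.10, 75 (65 and 10) under 0.01, and 76 (63 and 13) with at least 1.5-fold change. Leaving out 1 array gave 81 to 249 changed genes, 67 to 188 higher and 13 to 61 lower. Of the 167 genes, 166 were shared with the array weights, 136 with the setting without both arrays and 69 with the upper 50%. Probe set counts were 132, 758, 657 and, at 0.10, 343, and 104 to 356 with 1 array left out. The number of lists called was 0 by camera with an estimated correlation, 0 by fry's directional p (exact test per list: 0 adjusted, 1 at an unadjusted p under 0.05), 8 by fry's p for either direction, and 5 to 9 with 1 array left out. The camera call of DNA repair was lost in the upper 50% (adjusted p = 0.184) and without both cKO 2 and WT 4 (0.0921), and that of p53 targets without both (0.931), with array weights (0.185) and with the probe set of largest interquartile range (0.0514). Without both arrays the calls of G1/S, G2/M and the unfolded protein response stayed, with medians of -0.22, -0.12 and -0.14. The lowest correlation between arrays was 0.993, 0.980 in the upper 50% and 0.895 over the 1000 most variable genes.

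Ehmt2 at 1460692_PM_at kept its fall and its call in each setting (-3.03 to -2.78 with 1 array left out). Its other probe set stood at -0.0044 after median centring and at -0.0302 to 0.0449 with 1 array left out. The ranges were -0.0253 to 0.0935 for Ehmt1 and -0.0259 to 0.0944 for Wiz; Zfp644 stood at -0.0138 with probe sets averaged and at -0.0079 without both arrays, where Zbp1 stood at -0.0112. Of 683 alternative values of 39 genes given in the text that passed, 578 kept direction and call, 105 lost the threshold and 0 reversed. Of 392 of the 22 that did not pass, 27 passed and 8 had the other sign.

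Same-numbered arrays of the groups did not deviate together throughout (r = 0.14, 0.18, -0.59 and 0.31 for numbers 1 to 4), and 2 of 4 cKO arrays matched their own number best. With the replicate number as a block, 141 genes changed (112 higher, 29 lower), 119 of them shared, with 175 probe sets and 5 lists. The counts of changed genes were 151 without the lowest 25% by mean, 169 after quantile normalisation, 173 after median centring, 185 with a trend and 171 with either other rule for probe sets. Signal over background could not be assessed from these values.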

Other observations

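The tests of other cell types, of neighbouring genes, of the spread between arrays, of exchanged labels, of the exchanged pair in genes called without it, of the directions of neighbours and of X-linked genes, and the setting without both cKO 2 and WT 4, were chosen only after the results they bear on were seen. Afp, which encodes alpha-fetoprotein, rose by 1.80 (SE 0.17, limma adjusted p = 0.00118), from 5.62 ± 0.26 to 7.42 ± 0.32, while its 4 other probe sets changed by 4.004 and 2.73 and stood at 0.40 and 0.01, which did not pass. Snurf, which shares a transcript with the imprinted gene Snrpn, rose by 1.24 (SE 0.07, adjusted p = 0.000133). Of the 134 genes that rose and could be placed, 14 lie on the X chromosome (10.4%, against 3.52% of all 16936 placed genes), and 0 of the 32 that fell do. The odds ratio of these counts was 3.25 (95% interval 1.71 to 5.71), which describes them and tests no explanation; the largest of the 14 were Bex1 at 1.26 (SE 0.15) and Maob at 1.08 (SE 0.12). Neighbouring genes among the 14 are not independent. All 8 arrays were alike in Xist (4.50 to 4.59) and in the Y-linked genes Eif2s3y (8.99 to 9.55) and Kdm5d (6.71 to 7.50). These values argue against a difference in sex between the groups.

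The real grouping was not the one with the most changed genes. Of the 35 splits of the 8 arrays into 4 and 4, 2 gave at least 167 genes, the real one and the one that exchanges cKO 2 with WT 4, which gave 478; the other 33 gave 0. For probe sets it was also 2 of 35, with 210 and 846. By this count chance cannot be excluded for either number. A split with 2.86 times the real count points to a structure of the samples apart from genotype, whose source was not tested. Leaving out both arrays does not remove that structure, since the other 6 are parted alike by both splits: of 316 genes higher there, cKO 2 stood above WT 4 in 163, and of 114 lower, cKO 2 stood below in 37. Exchanged labels of cKO 2 and WT 4 are argued against by Ehmt2, which at 1460692_PM_at read 2.54 higher (log2) in WT 4 than in cKO 2, beyond 3 SD (1.08). For lists called by camera, 29 of 35 splits gave at least 5 and the highest other gave 15, so that chance cannot be excluded there.

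More genes rose than fell. An offset left by the normalisation stays open: the median log2 fold change of all genes was 0.0083, but quantile normalisation brings the arrays to a common centre and so fixes this value near 0. Cells of another type would bring their transcripts together, but the highest median over 15 lists of other types was 0.0367, with an upper quartile of members of at most 0.09; types outside these lists stay open. That genes silent in WT were switched on stays open: the median level of genes that rose, in the lower group, was 6.03, against 6.72 for genes that fell and 6.30 for all genes, and 55.6% of the genes that rose lay below the median of all genes, against 28.1% of those that fell. The difference of -0.69 (log2, two-sided permutation test, p = 0.0547) goes the way this explanation needs but missed the criterion of 0.05 set beforehand. The criterion took such a miss as evidence against it, which was wrong: a missed threshold does not show that the levels were alike, and levels of different probes without signal over background do not show which genes were silent. Whether the structure that sets cKO 2 with WT and WT 4 with cKO gives the excess could not be decided. A gene that follows it alone has cKO 2 below WT 4 by as much as the other arrays rise, give or take its spread. Of the 316 genes higher without both arrays, which were called without this pair, cKO 2 lay above WT 4 by at least 0.5 times the change in 109. As far on the other side of the expected place, below by at least 2.5 times the change, lay 1 (one-sided binomial test, p = 8.6e-32, with genes taken as independent). This comparison cannot decide it, since genes whose pair only scatters around 0 also lie far from that place. All genes were also read from the same pair of arrays, so the p-value does not measure the evidence. Set around 0, 109 of the 316 went the way of genotype and 106 the way of the exchanged split by at least 0.5 times the change. Of the 114 lower genes 24 went the way of genotype as far and 57 the other way. The sets of 316 and 114 were unequal before the pair was read, so 109 against 24 is no separate evidence for the excess. Loss of G9a, the difference that the design names, stays among the open explanations.

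Changed genes lay beside each other more often than random genes. Within 5 ranks in gene order 21 pairs of changed genes were found, against 8.10 on average and at most 20 in 10000 random sets (one-sided permutation p = 1e-04, the smallest these sets can give). Of the 21 pairs 17 went the same way, against 14.4 with directions shuffled among the changed genes (one-sided permutation p = 0.173). Similar genes read by the same probes may not account for all of it: 16 pairs share no symbol stem, against 7.81 on average (one-sided permutation p = 0.0065). Among them are Isoc1 with Minar2, Spata6 with Slc5a9, and Crlf2 with Plcxd1 and Gtpbp6. Snrpn and Snurf, which share a transcript, also count among the 16, and 4 of the 16 go opposite ways (Spata6 and Slc5a9 each with Skint10, Vldlr with Slc1a1, Selenow with Nop53). Crlf2, Plcxd1 and Gtpbp6 count as several pairs, as do Spata6, Slc5a9 and Skint10, so the pairs are not independent. The random sets were not matched for expression level, and changed genes were most frequent at middle levels. The p-values against random sets may therefore be too small. The region around Ehmt2 holds 0 changed genes among 45 measured, so none of the pairs lies there. With 0 changed genes the one-sided Fisher's exact test gives p = 1 by construction, so it does not show that the region is alike in the groups. Shared regulation of neighbours and a difference in genetic background between the groups at other places were not tested and stay open.

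Cell cycle genes stood lower in cKO by camera with the preset correlation. With an estimated correlation the adjusted p was 0.994 for G1/S and for G2/M. No single array decides the call with the preset correlation for the G1/S list, which kept its call whichever of the 8 arrays was left out (highest adjusted p = 4.7e-05, medians from -0.18 to -0.07). The list mean per array nevertheless did not pass the exact permutation test (p = 0.143), and the groups overlapped, with deviations from 0.05 to -0.19 in cKO and from 0.16 to -0.07 in WT. A missed threshold does not show that the groups are alike. Without both cKO 2 and WT 4, a setting chosen after the data were seen, the G1/S median was -0.22 (camera adjusted p = 3.5e-13). The remaining arrays are parted alike by genotype and by the exchanged split, so that setting cannot tell these apart. Variation between animals in the share of dividing cells was not measured and stays open, as does an effect of genotype on division.

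Of the 15588 probe sets unnamed here, 46 changed, 39 higher and 7 lower.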
